A study of Mus musculus with 2 samples.

How the data were processed

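The series holds H3K36me3 ChIP-seq from the stomachs of mouse embryos at 14.5 days, in 2 biological replicates of one group. Per the labels, each replicate is a pool of stomachs from males and females and joins 2 technical replicates, with a library size range of 300 to 500 bp. No other tissue, age, mark or treatment is in the series, and the control experiment that the labels name was not analysed here.

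The authors deposited 4 peak lists on the mm10 build, in the 10-column narrowPeak layout: 1 per biological replicate, 1 called on both replicates together (the pooled list), and 1 of replicated peaks. Per the text files deposited with the samples, the replicated list was derived from both replicate lists and the pooled list. The same text files name 2 inputs besides the alignments for the list of replicate 1 and 1 such input for the list of replicate 2, without stating their roles. The aligner, the peak caller, its version and its threshold are not given in the sources used here. Column 7 holds the signal value that the authors' peak caller gave each peak, and how it was normalised is not given in the sources used here. Columns 8 and 9 hold the deposited −log10 p and −log10 q of each peak. The lowest deposited −log10 p was 2.02 in both replicates and 2.03 in both series-wide lists, and the lowest −log10 q ranged from 0.410 in replicate 1 to 0.608 in the series-wide lists. A −log10 q of at least 2 was held by 59.4% of the peaks of replicate 1, 76.9% of those of replicate 2, 88.6% of the pooled list and 97.3% of the replicated list. Signal values, −log10 p and −log10 q were used to describe, rank or filter peaks within one list, and signal values also to set X peaks beside autosomal peaks of the same list.

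Peaks on chromosomes 1 to 19, X and Y were used. The 6 peaks of replicate 1, 8 of replicate 2, 8 of the pooled list and 3 of the replicated list that lay on other contigs were left out of the comparisons. Gene bodies, exons and gene classes came from GENCODE release M21, which annotates GRCm38, the assembly that mm10 is a name for. Chromosome lengths came from the RefSeq copy of GRCm38 patch 6. The covered share of a gene is the percent of its base pairs, from annotated start to end, that lie in peaks. A gene is called marked when that share is at least 20% in both replicates. Overlapping genes share peaks, and peaks carry no strand, so a covered share cannot be divided between genes that overlap: 1033 of the marked genes overlap another protein-coding gene. Read depth is unknown, because the files give no read counts. Intervals and detection limits that need a depth are therefore not given, and the absence of a peak says that none was called at this depth, not that the mark was absent.

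Peaks of the replicates were compared by the share of each replicate's peaks with at least 50% of their own length inside peaks of the other, and by the Jaccard index of base pairs. Chance was taken from 1000 circular shifts of the peaks along each chromosome, within the span from its first to its last peak in either replicate, with a one-sided permutation p whose smallest value is 0.000999. The same shifts were used for the share of peak base pairs in protein-coding gene bodies. Because the shifts keep all positions within the span of peaks, they also keep the chromosome of every peak. Values along genes were computed in marked protein-coding genes of at least 5 kb: the covered share of the first and the last of 3 equal segments, of exonic and intronic base pairs, and of the window of 1 kb on either side of the annotated start. They are given as the mean and SD over the replicates, with no test, since genes are not replicates. A difference between 2 libraries of one group has no further replicate, so differences between the replicates are also given without a test.

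The 22 gene lists and 5 gene families of the text were fixed before the data were examined, together with the thresholds, the alternatives and the rule for the genes named. The lists were ribosomal proteins, housekeeping genes, cell division, H3K36 methylation factors, stomach and foregut epithelium, squamous epithelium, gastric mesenchyme, smooth muscle, enteric neurons and glia, mature gastric secretory cells, endothelium, macrophages and leukocytes, erythroid cells, liver, pancreas and spleen, intestine, brain, skeletal and cardiac muscle, germ cells, imprinted genes, and Hox genes of groups 1 to 6 and of groups 9 to 13. All 336 listed symbols were found in the annotation, Cblif under its older symbol Gif. The median covered share of each list, over the mean of both replicates, was set against 10000 random lists of the same size drawn from protein-coding genes in the same of 10 length classes, with a two-sided permutation p adjusted by the Benjamini-Hochberg method over the 22 lists. These p-values place a list among the genes of these libraries and do not come from replicated groups. The rule for named genes took from each list the 4 genes listed first and any member on the other side of the 20% threshold from most of its list. It also took the 10 longest domains (replicated peaks merged across gaps of up to 1 kb), the 10 protein-coding genes of at least 5 kb with the highest covered share, the 5 such genes with the largest difference between the replicates in each direction, and the 10 replicated peaks with the highest signal value. Genes named outside it are said to have been chosen after their values were seen.

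The list test was tested on simulated data made from the 21938 protein-coding genes. Of 200 random lists of 15 genes, 1 passed 0.05 by its unadjusted permutation p with no change. After the members were raised by 5, 10 and 20 percentage points, 19, 98 and 199 passed. The calls of the text use p-values adjusted over the lists, so these counts can overstate what the adjusted test detects. Random lists often have a median near 0, so the test of the median could hardly place a list below chance. The mean in place of the median, the restriction to autosomal genes, 12 further gene families and the tests of individual patterns were added after the data had been seen. Several of those tests were changed once their first results were known. The X pairs went from 25 to 26 when Oga was matched to its older symbol Mgea5, and random sign flips were replaced by all of them. The signal values of X peaks were at first held unable to decide on X copies, and that test was given a bound it could miss. A joint verdict on Ghrl and Cd68 was divided, the 10 leading peaks were left out of the Zfp test, and tests of mesenchyme against epithelium and of the share of genes higher in replicate 2 were dropped, because they restated what had led to them. A test of the number of peaks was dropped because covered base pairs are the number of peaks times their width. The test of escape genes was extended to their differences from autosomal partners. The fixed symbol rule for histone genes of the clusters also took in variant genes outside them, so that family is called histone genes by symbol. The alternatives fixed beforehand were peaks with a −log10 q of at least 2, the same number of peaks from each replicate (the highest by −log10 p), sharing by 1 bp or by 50% of both peaks or of either peak, thresholds of 10% and 40% for marked genes, peaks merged across gaps of up to 500 bp, genes of at least 5 kb, random lists not matched on length, and each replicate alone. Sharing by 50% of both peaks was set against 100 shifts rather than 1000. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.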

Results

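Stomachs of mouse embryos at 14.5 days were profiled by ChIP-seq for H3K36me3, the trimethylation of histone H3 that lies over the bodies of transcribed genes. The 2 biological replicates were separate pools of stomachs from both sexes, and they form the only group of the series. The comparisons open to these data are therefore where in the genome and along genes the mark lay, which genes and gene groups carried it, and how far the replicates differed. Replicate 1 had 124589 peaks over 48.2 Mb (1.77% of the genome) and replicate 2 had 169508 peaks over 71.3 Mb (2.62%). The median peak was 299 bp wide in replicate 1 and 303 bp wide in replicate 2. Read depth was unknown for both.

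The peaks lay almost entirely in genes. Protein-coding gene bodies held 95.9% of the peak base pairs of replicate 1 and 95.7% of those of replicate 2, while they make up 38.2% of the genome. The share in gene bodies was 2.51 ± 0.00386 times their share of the genome (mean ± SD, n = 2). Peaks shifted along their chromosomes had 42.2% and 42.1% of their base pairs in gene bodies on average, and none of the 1000 shifts reached the observed share in either replicate (one-sided permutation p = 0.000999, the smallest they can give). When replicated peaks were joined across gaps of up to 1 kb they formed 37647 domains, of which 447 were at least 20 kb long and 996 (2.65%) touched no annotated gene of any class.

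The longest domains each covered most of a single large gene. The longest ran for 102 kb over Ubr4, a ubiquitin ligase gene, from position 139389338 to 139491317 of chromosome 4 (mm10). It took in 73.2% of the gene and ended beyond its annotated end, and peaks filled 72.5% of it in replicate 1 and 82.6% in replicate 2. Chd2, a chromatin remodeller gene, followed with 86.5 kb (chromosome 7, 73433291 to 73519824), and Trrap, which encodes a scaffold of histone acetyltransferase complexes, with 83.8 kb (chromosome 5, 144771062 to 144854870). The others among the 10 longest lay over Nedd4 (68.6 kb), Nup214 (65.1 kb), Ttc3 (63.1 kb), Gtf2i (60.9 kb), Brwd1 (57.9 kb), Dync1h1 (57.1 kb) and Nup160 (56.8 kb). Nup214 and Nup160 encode nuclear pore proteins and Dync1h1 the heavy chain of cytoplasmic dynein. The domain over Dync1h1 also overlapped the gene 1700001K19Rik.

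**Figure D1:**
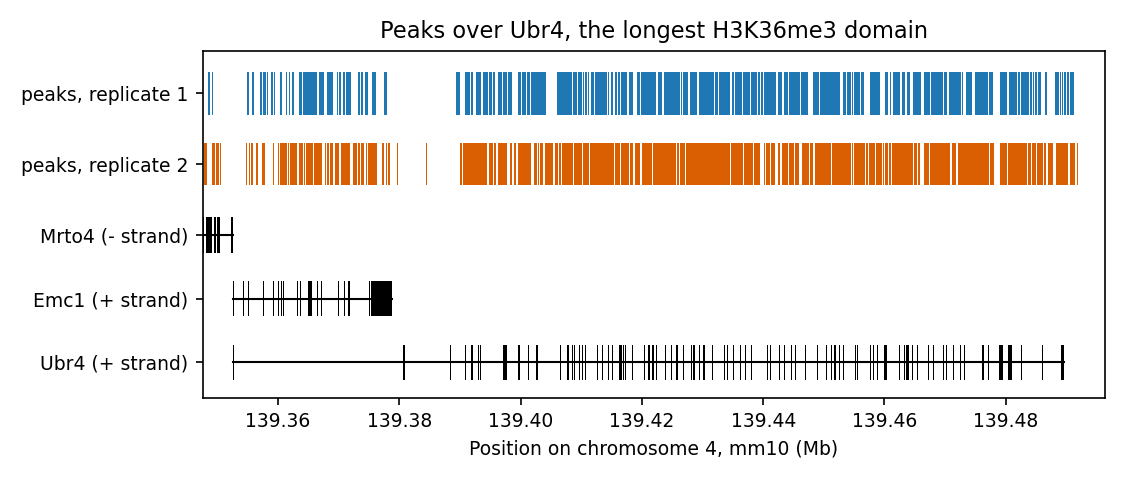
Peaks of replicate 1 (blue) and replicate 2 (orange) along chromosome 4 in mm10 coordinates, in Mb, above the genes of the region, with exons as black boxes. From position 139389338 onwards peaks filled 72.5% of the domain in replicate 1 and 82.6% in replicate 2, while the part of Ubr4 that overlaps Emc1 lies outside it.

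Within genes the mark was low at the start and rose toward the end. In the 3083 marked genes of at least 5 kb, the last of 3 equal segments of the gene was covered to 46.4% in replicate 1 and 60.1% in replicate 2, and the first to 16.0% and 23.1%. The last segment exceeded the first by 33.7 ± 4.61 percentage points (mean ± SD, n = 2), a difference larger than the spread between the replicates. It was the higher one in 2774 genes in replicate 1 and in 2822 genes in replicate 2. When each gene was divided into 20 bins, coverage was highest in bin 16 in replicate 1 (48.7%) and bin 17 in replicate 2 (62.7%). Beyond the annotated gene end it was still 27.9% and 39.1% in the first kb, and 9.03% and 13.04% in kb 5.

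The region around the start of these genes was nearly free of peaks. Within 1 kb of the annotated start, 0.595% of base pairs were in peaks in replicate 1 and 0.881% in replicate 2, against 32.9% and 44.0% of the gene bodies. The ratio of start to body was 0.0191 ± 0.00134 (mean ± SD, n = 2). Exons were more densely covered than introns, at 42.9% against 30.1% in replicate 1 and 55.2% against 40.9% in replicate 2, a ratio of 1.39 ± 0.0537. This ratio depended on which genes were called marked: it was 1.64 with a threshold of 10% of the gene body and 1.18 with a threshold of 40%. Base pairs were pooled over genes without regard to their position, and coverage rose toward the gene end. The ratio therefore does not separate exons from position along the gene or from gene length.

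**Figure D2:**
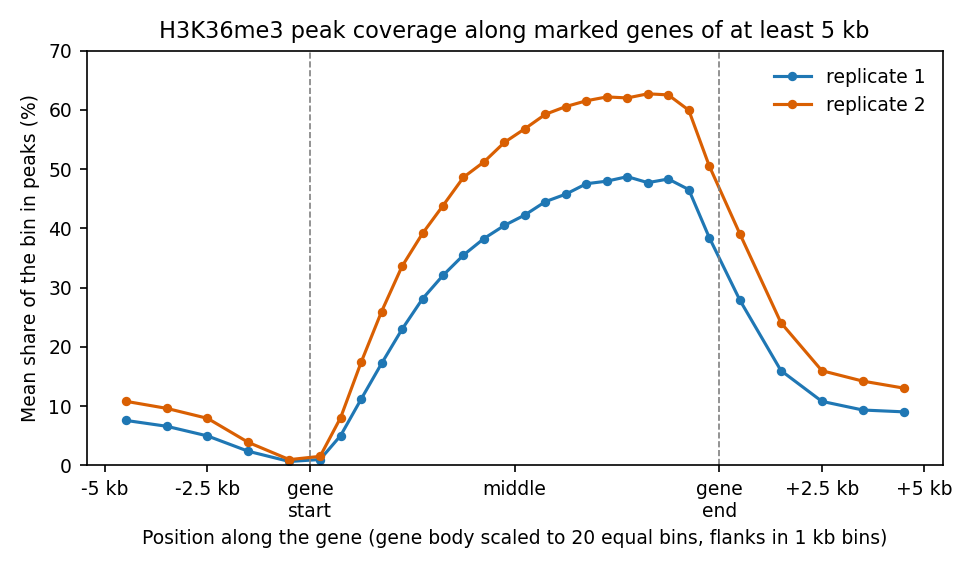
Mean percent of each bin in peaks, for replicate 1 (blue) and replicate 2 (orange), over 3083 marked genes of at least 5 kb. Gene bodies are scaled to 20 bins and 5 kb on either side are shown in bins of 1 kb, and coverage rises from 0.985% and 1.52% in the first bin to 48.7% and 62.7% at its highest.

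Of 21938 protein-coding genes, 3339 (15.2%) were marked in both replicates, and 10714 (48.8%) had no base pair in a peak of either. The median covered share of the marked genes was 32.1% in replicate 1 and 44.6% in replicate 2. Among genes of at least 5 kb the highest covered share was that of Fasn, the fatty acid synthase gene, with 76.9% of its body in peaks in replicate 1 and 86.8% in replicate 2 (chromosome 11, 120805846 to 120824547). Several genes of RNA splicing and RNA binding stood beside it: Sf3b3 with 80.2% ± 5.23 (mean ± SD, n = 2; chromosome 8, 110810239 to 110846787), Prpf8 with 80.2% ± 3.03 (chromosome 11, 75486816 to 75509449), Rbm5 with 79.9% ± 3.28 (chromosome 9, 107740371 to 107770996), Hnrnpab with 78.6% ± 3.68 and the RNA helicase gene Ddx17 with 77.2% ± 5.65. Another protein-coding gene overlaps 65.1% of Hnrnpab. The other 4 of the 10 were P4hb (77.8% ± 4.01), which encodes a protein disulfide isomerase, Hjurp (77.4% ± 6.79), which encodes the chaperone of the centromeric histone variant, Prrc2a (77.4% ± 4.62) and the nuclear import gene Kpnb1 (77.1% ± 3.51). Their order lies within the spread between the replicates. The number of marked genes depended on the threshold, with 5450 at 10% and 922 at 40% of the gene body.

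Most of the listed ribosomal protein and cell division genes carried the mark. Of 17 ribosomal protein genes 15 were marked, with a median covered share of 50.2% (adjusted permutation p = 0.00147, above nearly all random lists of like length). Rpl3, Rpl4, Rpl5 and Rpl7 had 23.1%, 48.8%, 59.2% and 22.0% in replicate 1 and 31.3%, 58.7%, 69.2% and 32.6% in replicate 2. The exceptions were Rps2 (18.5% and 18.7%) and Rps8, which had no peak in replicate 1 and 27.4% in replicate 2. Of 17 genes of cell division 16 were marked, with a median of 51.0% (adjusted permutation p = 0.00147). Mki67 and Top2a, both made in dividing cells, were covered to 47.8% ± 8.73 and 63.7% ± 15.5 (mean ± SD, n = 2), and the cyclin A gene Ccna2 to 34.4% in replicate 1 and 51.3% in replicate 2. The cyclin B gene Ccnb1 was the exception, with 14.9% and 31.4%. From 40% of the gene body 9 of the 17 were marked.

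The genes for the writers, readers and erasers of H3K36 methylation were themselves marked in 13 of 20 cases, with a median of 32.5% (adjusted permutation p = 0.00147). Setd2, the methyltransferase that places the third methyl group on this residue, was covered to 35.6% ± 7.41 (chromosome 9, 110532597 to 110618633), and Nsd1, Nsd2 and Nsd3 to 40.7%, 27.8% and 18.3% in replicate 1 and 53.0%, 37.3% and 29.3% in replicate 2. Besides Nsd3 the unmarked members were Kdm2b, Kdm4c, Dnmt3b, Msl3, Zmynd11 and Phf19, all under 15% in both replicates. From 40% of the gene body 3 of the 20 were marked. Of 16 housekeeping genes 8 were marked, and the list had a median of 28.5% (adjusted permutation p = 0.0066). Actb and Tbp were marked (45.6% ± 4.91 for Actb), Gapdh had 9.74% and 29.7%, and Hprt, which lies on the X chromosome, had 0.597% and 2.09%. Some unmarked members on autosomes, chosen after their values were seen, were far below the threshold too. Eef1a1 had no peak in replicate 1 and 9.47% in replicate 2, and Ubc had 0.283% and 6.13%. B2m had 3.71% and 10.1%, and Gusb 4.02% and 13.1%. From 40% of the gene body 5 of the 16 were marked.

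By its median, the stomach mesenchyme was the only cell compartment whose list stood above random lists, and several alternatives lost this call. Its share of marked genes did not set it apart from smooth muscle, where 3 of 15 genes were marked. Of all protein-coding genes 15.2% were marked. Of the 23 listed mesenchyme genes 5 were marked, and the list median was 12.8% (adjusted permutation p = 0.0343). The marked genes were Barx1, a homeobox gene of the stomach mesenchyme (22.0% ± 0.0806, mean ± SD, n = 2; chromosome 13, 48662998 to 48666507), the receptor gene Pdgfra (37.0% ± 10.7), the Hedgehog receptor gene Ptch1 (38.3% in replicate 1 and 56.0% in replicate 2), and the collagen genes Col1a1 (65.4% ± 17.3; chromosome 11, 94936224 to 94953042) and Col1a2 (41.4% ± 14.9). The forkhead genes were lower, with 12.3% and 14.4% for Foxf1, 5.24% and 3.24% for Foxf2 and no peak in Foxl1. Foxf1 and Foxl1 lie wholly within the annotated span of other protein-coding genes. The call of the gene list gastric mesenchyme was lost in replicate 1 alone, with peaks of −log10 q of at least 2, with gaps of up to 500 bp merged and with random lists not matched on length (adjusted permutation p = 0.0669, 0.0625, 0.0590 and 0.0528), with medians of 7.05%, 7.48%, 13.4% and 12.8%. With peaks of −log10 q of at least 2 the covered share of Barx1 was 7.48%, and 9 of the 23 genes were marked from 10% of the gene body, 1 from 40%, and 10 in replicate 2 alone.

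The genes of the stomach epithelium were not marked in any of 20 cases. Their median covered share was 2.03%, and 15 of the 20 had at least 1 base pair in a peak (adjusted permutation p = 1). Sox2, a transcription factor of the foregut, had no peak in either replicate. Its gene is only 2057 bp long, and the 1 kb around the start was nearly free of peaks even in marked genes. Gata4 and Gata6 had no peak in replicate 1 and 0.919% and 6.70% in replicate 2, and Foxa1 had 5.31% in replicate 1 and none in replicate 2. The median of the gene list stomach and foregut epithelium was 0.270% in replicate 1 alone, 0.610% with peaks of −log10 q of at least 2 and 1.23% with equal numbers of peaks. The list mean of 2.62% lay below that of random lists, while its median lay above theirs, so mean and median differ in direction. Smooth muscle genes did not pass the test (median 3.85%, adjusted permutation p = 1), and 3 of 15 were marked: Smtn (46.5% ± 11.1), the tropomyosin gene Tpm1 (48.6% ± 11.2) and Srf (44.2% ± 7.70), the last 2 of which are used outside muscle as well. Acta2, Actg2, Myh11 and Tagln, the first 4 genes of the list, had 4.28%, 2.06%, 2.24% and 3.11% in replicate 1 and 5.48%, 1.54%, 3.70% and 11.8% in replicate 2. The median of the smooth muscle list was 2.31% in replicate 1 alone, and from 40% of the gene body 1 of the 15 genes was marked.

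The remaining cell types of the stomach gave few or no marked genes, and none of their lists passed the test (adjusted permutation p = 1 for each). None of 15 genes of enteric neurons and glia was marked, and Phox2b, Phox2a, Ret and Ascl1, which mark the neural crest cells of the gut, had no peak. None of 13 endothelial genes was marked: Pecam1 had no peak, and Cdh5, Kdr and Tek had none in replicate 1 and 0.420%, 1.096% and 0.159% in replicate 2. Of 12 genes of macrophages and leukocytes only Cd68 was marked (20.5% and 40.1%), while Ptprc and Spi1 had no peak, Csf1r had 4.78% and 6.06%, and Cx3cr1 had 9.98% and 14.3%. Other protein-coding genes overlap 53.2% of Cx3cr1, so its peaks may be theirs. None of 12 erythroid genes was marked, with no peak in Hba-a1, Hbb-bs, Hbb-bt or Hbb-y. These named genes are only 955 to 1563 bp long. The 1 kb around the start was nearly free of peaks even in marked genes of at least 5 kb, so their lack of peaks says little. This limit bears, less strongly, on other short genes without peaks, such as Foxl1 (2705 bp) and Ascl1 (2842 bp). None of 11 squamous genes was marked, with 0.0960% of Trp63 covered in replicate 1, none in replicate 2, and no peak in Krt5, Krt14 or Krt15. Of 16 genes of mature gastric secretory cells, only Ghrl, the ghrelin gene, was marked (26.4% and 42.3%). The proton pump genes Atp4a and Atp4b, the intrinsic factor gene Gif and the pepsinogen gene Pgc had no peak. From 40% of the gene body neither Cd68 nor Ghrl was marked.

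Genes of other organs were almost free of peaks (adjusted permutation p = 1 for each list). All 12 liver genes, 12 genes of pancreas and spleen and 13 germ cell genes had no peak in either replicate, among them Alb, Afp, Apoa1 and Apoa2, Pdx1, Ptf1a, Cpa1 and Cel, and Ddx4, Dazl, Mael and Sycp1. None of 11 intestinal genes was marked, with no peak in Cdx1, Cdx2 or Fabp1 and 1.19% and 1.81% in Vil1. None of 14 brain genes was marked, with no peak in Snap25, Grin1 or Gria2 and 0.0390% of Syt1 in replicate 1. None of 14 genes of skeletal and cardiac muscle was marked, with no peak in Myod1, Myog, Ckm or Acta1. The limit for short genes holds here too, as for Apoa2 (1326 bp), Ptf1a (1839 bp), Apoa1 (1887 bp), Myog (2560 bp) and Myod1 (2626 bp). The medians of 14 of the 22 lists were 0. Because random lists of these sizes also had medians near 0, the test could not place these lists below chance.

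Position along the body axis and imprinting gave 2 further groups of genes. None of 18 Hox genes of groups 1 to 6 was marked, and 5 of them had peaks, while all 16 Hox genes of groups 9 to 13 had none (adjusted permutation p = 1 for both). Hoxa1, Hoxa2 and Hoxa4 had no peak and Hoxa3 had 3.10% and 6.98%; Hoxa9, Hoxa10, Hoxa11 and Hoxa13 had none. The list of imprinted genes did not pass (median 4.39%, adjusted permutation p = 1), and of its 16 protein-coding members only Igf2r was marked (22.0% and 40.6%). Igf2 had 15.9% and 24.1%. Of the 16 imprinted genes 5 were marked in replicate 2 alone. From 10% of the gene body 5 of the 16 imprinted genes and 1 of the 18 Hox genes of groups 1 to 6 were marked, and from 40% none. Of the noncoding members, Meg3 reached the threshold in both replicates (24.9% and 40.6%), while H19 had no peak in replicate 1 and 34.8% in replicate 2.

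**Figure D3:**
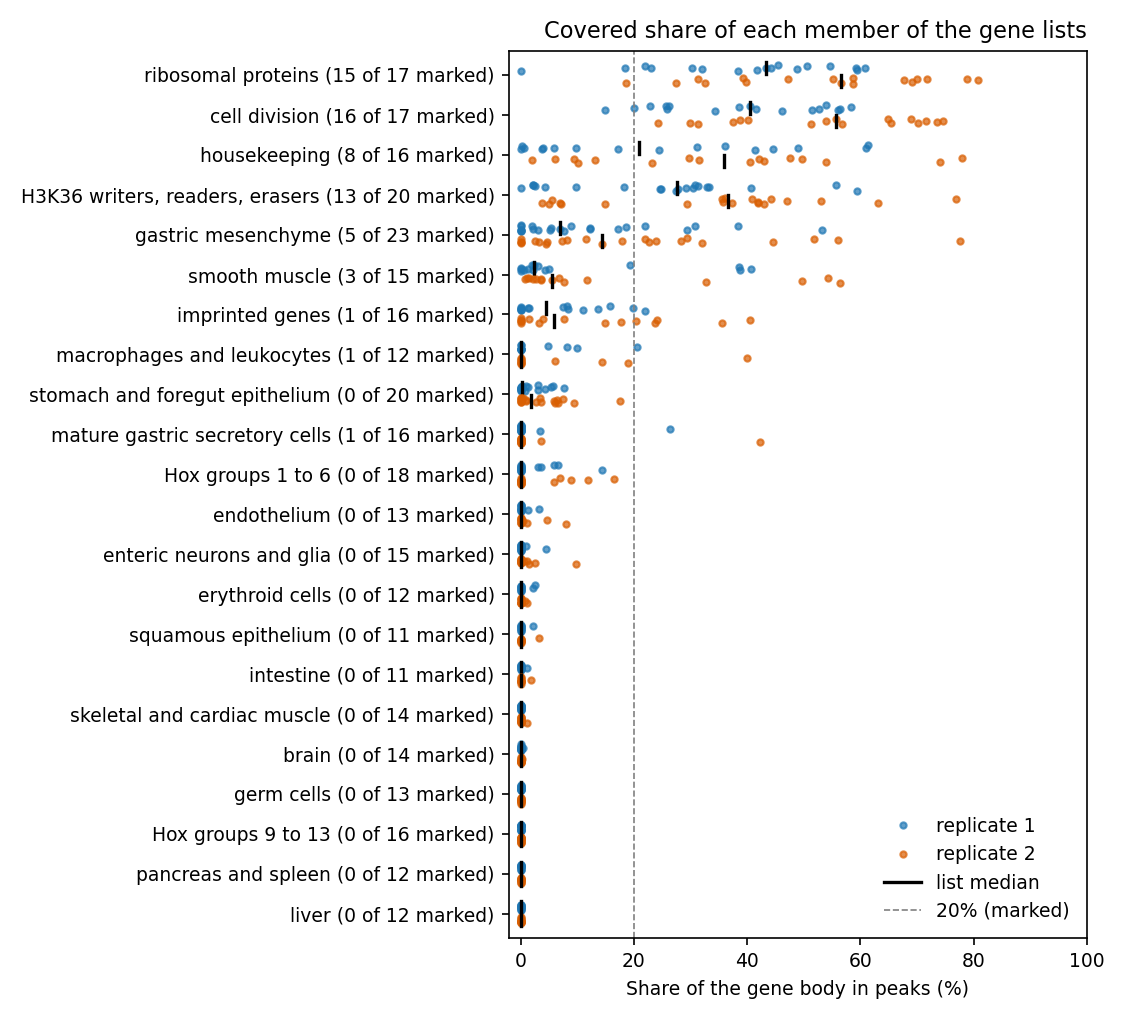
Percent of the gene body in peaks for each protein-coding member of the 22 lists, replicate 1 in blue and replicate 2 in orange, with the median of each list and replicate as a black bar and the 20% threshold as a dashed line. The ribosomal list had 15 of 17 members marked and the cell division list 16 of 17, while the lists for liver, for pancreas and spleen and for germ cells lie at 0 throughout.

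The receptor gene families of the olfactory and vomeronasal organs had no marked gene. None of 1135 olfactory receptor genes and none of 331 vomeronasal receptor genes was marked. None of 57 clustered protocadherin genes was marked, and 36 of them had no peak. Of 95 histone genes taken by symbol 2 (2.11%) were marked, the variant genes H2afv (36.7% in replicate 1 and 47.9% in replicate 2) and H2afy (28.1% and 48.7%), named after their values were seen. They are not genes of the histone clusters, and none of the 67 genes with a Hist symbol was marked. These families were not set beside genes of like length. Of 394 Zfp genes, which encode zinc finger proteins, 104 (26.4%) were marked, against 15.2% of all protein-coding genes. The marked share changed with the threshold in 3 gene classes: zinc finger Zfp genes (45.2% at 10% and 7.87% at 40% of the gene body), clustered protocadherins (3.51% at 10%, and in replicate 2 alone) and histone genes (3.16% at 10% and 0% at 40%). Among annotated classes, 61 of 5854 lincRNA genes (1.04%), 68 of 9940 processed pseudogenes (0.684%) and 150 of 1507 snoRNA genes (9.95%) were marked. A marked protein-coding gene, whose peaks they share, overlapped 114 of those 150 snoRNA genes, 29 of the 61 lincRNA genes and 32 of the 68 processed pseudogenes.

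The 10 replicated peaks with the highest signal value of the authors lay at genes, many over a last exon. The first was a peak of 3666 bp over the last exon of Zfp157 (chromosome 5, 138455442 to 138459107; signal value 11.0), and 88.2% of it was exonic. The next lay over the last exon of Zfp865, in a stretch that also holds Gm44973 and Ccdc106 (chromosome 7, 5028586 to 5032644; signal value 10.3). Zfp146 and Zfp810 followed lower in the order, with signal values of 9.74 each and peaks over their last exons. The others lay at Cnbp (10.1), Hnrnpul2 (9.99), Ankhd1 (9.96), Serinc1 (9.91), the transcribed locus Trerf1 (9.91) and Eif4g2 (9.72).

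Marked genes were spread over all autosomes and nearly missing from the sex chromosomes. On autosomes 3334 of 20807 protein-coding genes (16.0%) were marked, from 11.7% on chromosome 13 to 20.2% on chromosome 5. On X 5 of 948 (0.527%) were marked, and on Y none of 183. Chosen after their values were seen because they are so few, the 5 genes on X were the filamin gene Flna (28.4% in replicate 1 and 57.7% in replicate 2), Ddx3x (29.8% and 41.3%), Maged1 (29.7% and 41.0%), Hcfc1 (21.8% and 45.1%) and Kdm5c (24.8% and 39.4%). The mean covered share over all genes was 7.92% and 11.6% on autosomes and 0.896% and 2.14% on X. The pools held both sexes.

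**Figure D4:**
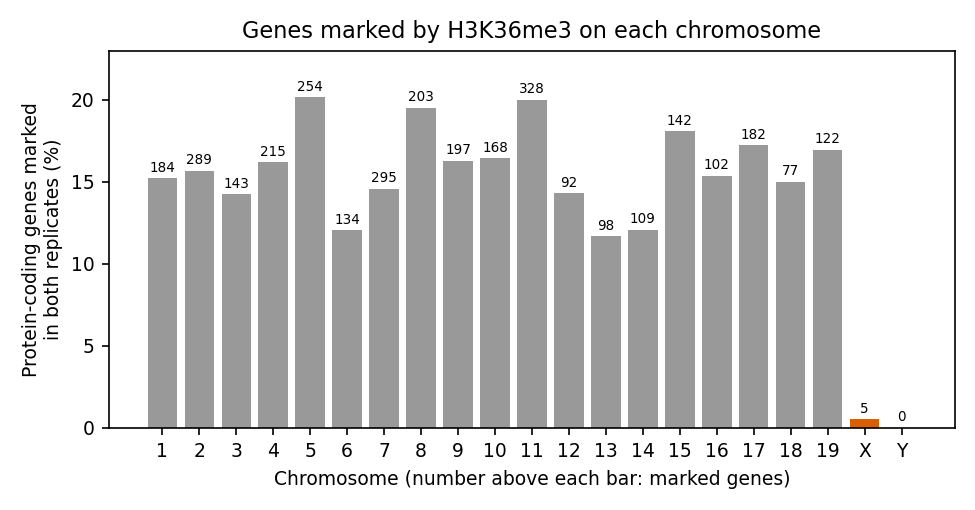
Percent of protein-coding genes marked in both replicates, by chromosome, with the number of marked genes above each bar. The autosomes lie between 11.7% and 20.2%, X (orange) is at 0.527% and Y at 0.

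The replicates shared their pattern and differed in extent. Of the peaks of replicate 1, 60.9% had at least 50% of their length inside peaks of replicate 2, and of those of replicate 2, 35.9% inside peaks of replicate 1. Shifted peaks gave 3.16% and 2.05% (one-sided permutation p = 0.000999, the smallest the 1000 shifts can give). The mean of both shares was 48.4%, and it was 27.1% when 50% of both peaks had to overlap. The Jaccard index of base pairs was 34.1%. Across genes, which are not independent replicates, covered shares of the replicates had a Spearman correlation of 0.939 and a Pearson correlation of 0.954. Both include the 10714 genes with no peak base in either replicate, so they do not describe genes with peaks alone. Replicate 2 covered 1.48 times the base pairs of replicate 1 and had the larger share in 3191 of the 3339 marked genes (95.6%), with a median difference of 11.3 percentage points and an SD over genes of 7.27. With equal numbers of peaks the median difference was 7.49 points. Only replicate 1 put 56 genes over the threshold, and only replicate 2 put 1656.

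The 10 genes with the largest differences were between 5136 and 9410 bp long, against a median of 18064 bp for marked genes. Shmt2, a mitochondrial enzyme gene of one-carbon metabolism, had 9.43% in replicate 1 and 51.9% in replicate 2, and Retreg2 had 25.5% and 67.8%. March9 (4.45% and 42.0%), Rbm15b (3.84% and 41.2%) and Dmap1 (23.2% and 60.2%) came next. In the other direction Haghl had 47.2% and 28.6%, Amt 17.5% and none, Slc39a5 21.1% and 4.66%, Efna1 18.5% and 3.24%, and Tma7 24.7% and 9.80%. Rbm15b and Slc39a5 lie wholly within the span of other protein-coding genes, and such genes overlap 59.9% of Haghl. With 1 library on each side, none of these differences could be tested.

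The 2 series-wide lists related to the replicates in different ways. The pooled list held 169883 peaks over 89.95 Mb and the replicated list 108728 peaks over 74.6 Mb, and all 108728 replicated peaks had the exact coordinates of a pooled peak. Of the replicated peaks, 43.6% had at least 50% of their own length covered in each replicate, and 26.4% of the deposited replicated list did when only peaks of −log10 q of at least 2 were used. When 50% of either peak was enough, 68762 (63.2%) met the rule, and 0 of the 61155 other pooled peaks did. The other 39966 replicated peaks did not meet it, and 3104 of them touched no peak of either replicate.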

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

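The files of the replicates held peaks outside the 21 chromosomes that were compared. Replicate 1 had 6 such peaks and replicate 2 had 8. They are listed because any count over 3 was, which does not make them unusual, and the control experiment that the labels name was not analysed here. Most lay on 1 contig that the files assign to chromosome 4, with 4 peaks in replicate 1 and 6 in replicate 2. No explanation was tested for them. A group of 2 libraries is too small for a test of a single library standing apart.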

How the results depend on the processing

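Tests with the mean of a list, with autosomal genes alone and with autosomal marked genes were chosen after the data had been seen, as was the spread over autosomes that the Spearman correlation was judged by. Of 176 comparisons of a list's call with its call under an alternative, 159 gave the same call. With the mean in place of the median 18 lists passed, 5 above and 13 below random lists, instead of 5. Epithelium turned to below chance (mean 2.62%, adjusted permutation p = 0.0201), and these lists passed as lower: squamous epithelium 0.247%, enteric neurons and glia 0.702%, gastric secretory cells 2.37%, endothelium 0.728%, erythroid cells 0.282%, intestine 0.141%, brain 0.0300%, skeletal and cardiac muscle 0.0570%, and liver, pancreas and spleen, germ cells and Hox groups 9 to 13, each 0%. The cause lies in the statistic, since medians of random lists are near 0 and their means are not. The gene list gastric mesenchyme lost its call with peaks of −log10 q of at least 2 (median 7.48%, adjusted permutation p = 0.0625), with gaps of up to 500 bp merged (13.4%, 0.0590), with random lists not matched on length (12.8%, 0.0528) and in replicate 1 alone. Its medians in the single replicates were 7.05% and 14.4%, and the cause was not tested. The other 4 lists above chance kept their call in every alternative run.

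Replicate overlap (mean 27.1% to 63.5%), the share of peaks in gene bodies (2.51 to 2.52 times that of the genome), the excess of the last over the first gene segment (29.5 to 36.6 percentage points) and the median difference between the replicates (7.49 to 14.9 points) kept their direction under all alternatives run. With −log10 q of at least 2 the ratio for promoter against gene body was 0.0171, the value of replicate difference: Spearman across genes 0.911, and the share of the deposited replicated list met in both replicates 26.4%. That share was 36.7% with equal numbers of peaks, 64.7% when 1 bp was enough and 63.2% with 50% of either peak, since each rule changes what counts as met. With marked genes from 10% of the body, the ratio for exon against intron was 1.64, the promoter ratio 0.0256, and the marked genes 5450, with 45.2% for gene classes: zinc finger Zfp genes, 3.51% for gene classes: clustered protocadherins and 3.16% for gene classes: histone genes by symbol. From 40% these were 1.18, 0.0207, 922, 7.87%, and 0% of histone genes. Each replicate alone gave exon ratios of 1.42 to 1.48, promoter ratios of 0.0194 to 0.0240, 26.6% to 39.1% of Zfp genes, 0% to 3.51% of protocadherins and 2.11% to 3.16% of histone genes. For thresholds the shift follows from the genes they admit, and for single replicates the cause was not tested. All 2330 genes marked with −log10 q of at least 2 and all 3261 with equal numbers of peaks were among the 3339, and all 3339 were among the 4050 with gaps merged. No paired analysis was possible because the series has 1 group. Depth is unknown, so how far it limits these values could not be told.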

Other observations

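The tests of the 12 gene families, of Zfp genes and of X copies were chosen after the results had been seen, and those of the X pairs, of escape genes and of Ghrl and Cd68 were changed after their first results. Beyond the lists fixed beforehand, families of protein-coding genes taken by symbol were set against length-matched random lists in the same way. All 7 families of general cell machinery lay above chance (adjusted permutation p = 0.000343 for each over the 12 families). Besides ribosomal proteins, 34 of 55 translation initiation factor genes were marked, led by Eif3d (71.4% in replicate 1 and 76.1% in replicate 2), as were 23 of 39 proteasome genes, led by Psmc4 (56.8% and 68.1%). Of 94 genes of the respiratory chain and ATP synthase 35 were marked, led by the ATP synthase gene Atp5a1 (59.6% and 73.6%). Of 24 nuclear pore genes 17 were marked, led by Nup88 (61.0% and 67.4%), and of 45 chromatin remodeller genes 29, led by Chd4 (60.9% and 78.6%). Nup214, Nup160 and Chd2, already seen among the longest domains, were not left out of their families. Nor was Eif4g2, already seen among the strongest peaks, left out of the translation initiation factors. The ribosomal family contains the list fixed beforehand. The other 5 families did not pass by their median (adjusted permutation p between 0.271 and 1). By their mean, 3 of them lay below random lists: Wnt ligands and frizzled receptors with 3.13% (adjusted permutation p = 0.00384), potassium channels with 0.668% and cytokines and chemokines with 1.84% (0.000267 each). Collagens had 6 of 44 genes marked, among them Col6a1 (38.8% and 58.5%), and integrins and laminins 4 of 42, among them Lamb1 (52.3% and 72.2%). None of 29 genes for Wnt ligands and frizzled receptors was marked, with Fzd4 (13.8% and 34.2%) and Wnt5a (12.3% and 29.3%) highest. None of 94 potassium channel genes was marked, and 2 of 113 genes with cytokine and chemokine symbols were, Il18bp and the receptor gene Il6st.

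Splicing factor genes were frequent among the genes with the highest covered share, which led to the hypothesis that they lie above genes of like length as a group. Without the 4 genes that led to it, 68 of 97 were marked, and their median of 35.95% lay above random lists (adjusted permutation p = 0.000343). They may be one of several families of abundant cell machinery with this property, since the other 6 passed as well. Zfp genes held 4 of the 10 peaks with the highest signal value. Without those 10, 46 of the 1077 strongest peaks (4.27%) overlapped a Zfp gene, against 1.98% of the other 107641 replicated peaks (Fisher's exact p = 2.76e-06, over peaks, which are not independent). In the 104 marked Zfp genes the last exon was covered to 54.2% in replicate 1 and 65.2% in replicate 2, and the rest of the gene to 28.5% and 38.9%. Last exons of other marked genes were not measured, so this is not shown to be particular to Zfp genes. Over all marked genes of at least 5 kb, the last of 3 equal segments had 46.4% and 60.1%, against 16.0% and 23.1% in the first. Genes of the mesenchyme list had a mean covered share of 16.1% ± 17.5 (SD over 23 genes) and those of the epithelium list 2.62% ± 2.80 (20 genes). They differed by 13.4 percentage points, and this difference was not tested.

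The low share of marked genes on X (Fisher's exact p = 1.36e-61 against autosomes, over genes, which are not independent) was weighed against 3 explanations. A larger share of silent genes on X is argued against as the only cause. In 26 broadly used X genes set beside autosomal genes of the same complex or family, the median difference was −23.7 percentage points. Of these genes, 24 were lower on X. The mean difference was −23.8 points (exact sign-flip permutation p of the mean = 9.24e-07). The pairs do not show how many other X genes were silent, so a contribution of silent genes to the low share stays open. X inactivation and fewer X copies cannot be told apart, since 4 escape genes decide little: the listed genes that escape it averaged 23.2% and the other 22 listed X genes 11.6%, a difference of 11.6 points (exact permutation p = 0.0377), but set against their autosomal partners the means were −24.1 and −23.7 points, a difference of −0.352 points (exact permutation p = 0.971). Fewer X copies in a pool of both sexes stays open. The median signal value of X peaks minus that of autosomal peaks was −0.261 on average and negative in both replicates. X inactivation or any other weaker marking of X would give this as well, so the signal values do not favour fewer copies. Control coverage was not analysed here, and no biological explanation beyond these was tested.

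Ghrl and Cd68 were the only marked members of their lists, and peaks that belong to a neighbouring gene were weighed as the cause. For Ghrl, 0.0% of its covered base pairs lay inside or within 2 kb of another marked protein-coding gene. This argues against a marked gene within that distance as the source. Peaks from unmarked genes or from genes further away were not examined. Marked genes of at least 5 kb still had 9.03% coverage in replicate 1 and 13.04% in replicate 2 in kb 5 beyond their end. For Cd68, 64.6% of the covered base pairs lay inside or within 2 kb of another marked gene, next to Eif4a1 and Mpdu1. This share lay between the bounds set beforehand, so the peaks of Cd68 and of its neighbours cannot be told apart. Both genes are short (3762 and 1941 bp) and neither stayed over the threshold when it was 40%. No biological explanation was tested.

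Replicate 2 covered 1.48 times the base pairs of replicate 1. It had 1.36 times the peaks. With equal numbers of peaks drawn at random from each replicate it covered 1.09 times the base pairs (SD 0.0014 over 100 draws). Such draws leave only the difference in mean peak width. With equal numbers of the highest peaks by −log10 p, the rule fixed beforehand, replicate 2 covered 1.24 times the base pairs. How much of the difference comes from the number of peaks therefore depends on which peaks are taken. Depth, antibody performance and the unlike inputs named for the 2 lists were not tested.

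Of the 996 domains outside annotated genes, the 5 longest, chosen after the data had been seen, all lay just beyond the 3′ end of a protein-coding gene. The longest had 5895 bp (chromosome 9, 73123355 to 73129249) and began 21 bp from the end of Rsl24d1, and the next had 4459 bp (chromosome 6, 117925684 to 117930142), 61 bp from the end of Hnrnpf. The others lay 870 bp from Ahcyl1, 112 bp from Zc3h11a and 176 bp from Kctd3.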
